A study of Caenorhabditis elegans with 12 samples.

How the data were processed

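Per the labels, gene expression was profiled by RNA sequencing of cells sorted from C. elegans larvae that carried dsRed under the F16F9.3 promoter, which is active in amphid sheath (AMsh) glia. Wild type animals (strain OS4079) and che-2(e1033) animals (strain OS11549), which lack normal sensory cilia, were each grown as 3 synchronised cultures at 20 °C for 36 to 42 h, to the L3/L4 stage. Each culture was dissociated and sorted into dsRed-positive cells (the AMsh fraction, 168356 to 240125 events, 0.1 to 0.4% of all events) and dsRed-negative cells (the non-AMsh fraction). The 0.4 to 5 ng of total RNA was amplified with a SMARTer kit and sequenced on a HiSeq 2000. This gave 12 libraries in 4 groups of 3, with 1 library of each group under each of the replicate codes E30, E35 and E36. The labels are not free of conflict. Except for wild type non-AMsh, the titles of the E36 libraries carry the same replicate number as those of E30. The column names of the E35 libraries contain E36, and those of E30 follow another naming style. Libraries were assigned by the codes in their titles and in the header above the columns.

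The authors processed the reads with CASAVA 1.8.2 and FastQC, aligned them with STAR 2.3 to WBcel235, and counted them per gene with featureCounts. The deposited table holds whole-number read counts per gene and library, with no normalisation, and the summed exon length of each gene as a further deposited column in bases, which was not used. The strand setting, the annotation release and any read filter were not given in the sources used here. The table lists 46726 genes, 43623 of them with a symbol in the reference gene names, and 46364 identifiers were found in the reference annotation, all on the same chromosome. No count was recorded in any library for 22353 genes. Library totals ranged from 15420762 to 26019499 counts, so a gene with no count in a library had a level of at most 0.115 to 0.195 CPM, the level relative to the library total (3 counts of the total). These limits, the counting intervals of ratios and the folds written as "at least" (3 counts over the group of 3 libraries in place of 0) cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Gene symbols and identifiers are those of the reference; positions are those of the deposited table on WBcel235.

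Counts were scaled with the trimmed mean of M values (TMM), and genes with enough counts by filterByExpr for the 4 groups were kept (16690 genes). A single quasi-likelihood negative binomial model of the 4 groups was fitted with edgeR 4.0.16 in R 4.3.3 (8 residual degrees of freedom, biological coefficient of variation 0.732), and the p values (2-sided) were adjusted by Benjamini-Hochberg within each comparison at a false discovery rate of 0.05. The 5 comparisons were the fractions in wild type, the fractions in che-2, che-2 against wild type in the AMsh fraction, the same in the non-AMsh fraction, and the difference between these last changes. Levels are CPM of TMM-scaled library sizes, as mean ± SD of 3 libraries, and each log2 fold change is given with its standard error (SE). Values, tests and figures came from R with limma 3.58.1 and DESeq2 1.42.0, and from Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

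The comparisons, tests, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Named genes were, per comparison, the up to 10 with the largest rise and the up to 10 with the largest fall (5 for the difference between changes and for the fractions in che-2) among those with an adjusted p under 0.05, a mean of at least 5 CPM over the 12 libraries and no overlap between the replicates of the groups. Where no gene passed, the 5 with the smallest p were taken and are given as not passing. The rule added che-2, the AMsh markers F16F9.3, T02B11.3, fig-1, vap-1 and ver-1, and up to 4 passing members of each gene list with the smallest p, or the single member with the smallest p where none passed. Of 32 lists with measured members, the 31 with at least 5 were tested with camera (preset inter-gene correlation 0.01, and an estimated correlation as a second value) and with fry (a directional test, and a mixed test for changes in either direction), Benjamini-Hochberg adjusted over the lists in 4 of the comparisons. The fractions in che-2 were given as counts of list members only. Members that passed when p values were adjusted over the list alone are given beside those that passed over all genes tested.

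Both fractions of a culture come from the same animals, so the fractions are paired by culture. After group means were removed, the correlation across genes between the fractions of a culture was 0.203 to 0.273 in wild type and 0.159 to 0.503 in che-2, each above the values for other cultures (3 of 3 in each genotype), and values with the culture as a block are given beside the comparisons of fractions. Wild type and che-2 cultures that share a replicate code are different animals.

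The pipeline was tested on simulated counts with the gene-wise spread and the depth of these libraries, without outlying libraries or effects of the culture. Folds were applied to the whole fraction, so the recoveries do not cover a change in only part of its cells. Changed genes had a mean of at least 5 CPM, so the recoveries do not cover genes at lower levels. For che-2 against wild type in the AMsh fraction, edgeR recovered 10% of genes changed 4-fold, 76% of those changed 16-fold, 100% at 64-fold and 98% at 256-fold, with 5 unchanged genes called. DESeq2 recovered 50% at 4-fold with 81 unchanged genes called, and limma-voom 16% with 4. For the difference between changes, edgeR recovered 4% at 4-fold, 54% at 16-fold and 94% at 64-fold, with 1 unchanged gene called. Of 21 simulated lists, the 1 list moved 4-fold was called, which the run required in order to finish, and 0 of the others. The simulated genes varied independently, whereas members of the real lists vary together (estimated correlation 0.545 for sperm genes). The simulation therefore does not measure false calls of the real lists.

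Alternatives were another scaling (DESeq2 size factors, upper quartile), no filter on low counts or a stricter one (at least 5 CPM in 3 libraries), the replicate code or the culture as a block, robust dispersion, DESeq2, limma-voom with sample weights, only the libraries of the groups compared, a false discovery rate of 0.1, a 2-fold minimum, and each library and each replicate code left out in turn. A fit without the 2 libraries with the fewest detected genes was added after the data were seen. No library was left out of the comparisons.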

Results

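RNA sequencing counts were compared between AMsh glia, which ensheathe the sensory endings of the amphid neurons, and all other cells of wild type and che-2(e1033) larvae. che-2 encodes a protein of intraflagellar transport, and the series asks how AMsh glia respond when the cilia of the neurons they contact are lost. The 12 libraries fall into 4 groups of 3: wild type AMsh, wild type non-AMsh, che-2 AMsh and che-2 non-AMsh. For codes E30, E35 and E36 in this order, the totals were 25450178, 25423855 and 25073137 counts for wild type AMsh and 24987767, 21073927 and 26019499 for wild type non-AMsh. They were 21790665, 20783265 and 23178841 counts for che-2 AMsh and 15420762, 16383443 and 18211377 for che-2 non-AMsh. A pair of libraries stood apart: wild type AMsh E30, with 14101 genes detected, and che-2 AMsh E35, with 15711 genes detected and 6.88% of counts from ribosomal RNA genes, against 17555 to 19298 genes detected in the others. Mitochondrial genes took 10.5 to 21.6% of the counts.

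The targeted gene che-2 (WBGene00000484, chromosome X, 481378 to 486504) had few counts in every library. Its level was 0.485, 3.77 and 0.285 CPM in the wild type non-AMsh libraries E30, E35 and E36, and 0, 2.18 and 0.666 CPM in the wild type AMsh libraries. In che-2 it was 1.28, 3.71 and 0.281 CPM in the non-AMsh libraries and 0.669, 12.5 and 4.69 CPM in the AMsh libraries. The library with no che-2 count allows at most 0.118 CPM. The transcript was detected in the mutant. Neither its AMsh change (5.97 ± 6.04 in che-2 against 0.9498 ± 1.12 CPM in wild type, SD, n = 3, log2 fold change 2.64, SE 1.59, adjusted p = 0.525) nor its non-AMsh change (1.76 ± 1.77 against 1.51 ± 1.96 CPM, log2 fold change 0.21, SE 1.51, adjusted p = 0.987) passed the test.

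The comparison of fractions in wild type shows what the sort enriched. F16F9.3 (WBGene00017514, chromosome X, 8457638 to 8459840), whose promoter drives the sorted reporter, was at 173 ± 70.4 CPM in AMsh and 6.31 ± 2.62 CPM in non-AMsh libraries (SD, n = 3, log2 fold change 4.78, SE 0.67, adjusted p = 0.0102). T02B11.3, another gene used as an AMsh reporter, was at 1319 ± 702 against 90.03 ± 17.5 CPM (3.87, SE 0.72, adjusted p = 0.0408). fig-1, which encodes a secreted AMsh protein, was at 157.6 ± 47.7 against 10.2 ± 1.796 CPM (3.95, SE 0.67, adjusted p = 0.0226), and vap-1, a secreted AMsh venom-like protein, at 904 ± 733 against 16.9 ± 4.97 CPM (5.75, SE 1.08, adjusted p = 0.0434). With the culture as a block, fig-1 (adjusted p = 0.0572, and 7.04e-08 to 1.00 over the alternatives run) and vap-1 (0.0956, and 2.57e-08 to 1.00) did not pass. ver-1, a receptor tyrosine kinase gene, was at 5.82 ± 8.64 CPM in AMsh libraries against 3 counts in the non-AMsh group (ratio interval 46.4 to 665) and did not pass (adjusted p = 1.00). Among the genes with the largest enrichment, F35B12.9 (WBGene00009388, chromosome V, 11601119 to 11602360) reached 1637 ± 901 against 27.2 ± 7.29 CPM (5.91, SE 0.74, adjusted p = 0.00762). srlf-32 reached 1555 ± 984 against 34.8 ± 7.77 CPM (5.48, SE 0.78, adjusted p = 0.0105).

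In all, 72 genes were higher and 1 lower in wild type AMsh libraries (636 at an unadjusted p under 0.05). All 73 had no overlap between groups, as had 8.65% of the tested genes, where chance gives 10% for 3 against 3. The largest log2 enrichments were 7.14 (SE 1.35) for C18D1.2, 6.29 (SE 0.99) for F59D12.3, 6.14 (SE 0.90) for C12D5.9 and 6.07 (SE 0.94) for the lectin gene clec-199. C15B12.4 (5.66, SE 0.85), R05A10.3 (5.598, SE 0.68) and ZK105.12 (5.41, SE 0.72) completed the highest 10, with adjusted p from 0.00762 to 0.0434. With the culture as a block, C18D1.2 (adjusted p = 0.239, and 4.08e-08 to 1.00 over the alternatives run) and F59D12.3 (0.0529, and 2.79e-12 to 1.00) did not pass. The gene lower in AMsh libraries was WBGene00017211 (−4.32, SE 0.81, adjusted p = 0.043), which did not pass with the culture as a block (adjusted p = 0.0654, and 3.83e-06 to 1.00 over the alternatives run). With the culture as a block 75 genes were called, all of them higher, and with the replicate code as a block 65. DESeq2 called 176 genes, 147 higher and 29 lower. Leaving out single libraries gave 0 (without wild type non-AMsh E35 or E36) to 91 genes (without che-2 AMsh E30). It gave 19 without wild type non-AMsh E30 and 42 without wild type AMsh E35. Without the 2 libraries with the fewest detected genes, 111 genes were called.

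Of 22 fixed AMsh markers, 5 were higher in wild type AMsh libraries (7 higher and 1 lower adjusted over the list alone), with a list median of 0.48. Besides the genes above, these included ttx-1, an Otx-type homeobox gene (24.6 ± 10.6 against 3.00 ± 0.764 CPM, 3.03, SE 0.56, adjusted p = 0.0384, and 0.0793, not passing, with the culture as a block). The list was higher by camera (adjusted p = 1.73e-08, and adjusted p = 0.0418 with an estimated correlation) and by the directional test of fry (adjusted p = 0.0347). With the replicate code as a block it was the 1 list called, but its adjusted p with an estimated correlation was then 0.097. Over the alternatives run, this adjusted p was 0.0526 to 0.981. The lists were not tested with the culture as a block. In the amphid channel and dendrite anchoring list, fig-1 was the 1 higher member of 12 (also adjusted over the list alone, list adjusted p = 0.678). The other 29 tested lists were not called in this comparison. kcc-3, a potassium-chloride cotransporter gene of AMsh glia (134 ± 52.2 against 29.6 ± 16.8 CPM, 2.17, SE 0.60, adjusted p = 0.412), and irg-2 (67.7 ± 51.6 against 5.13 ± 3.32 CPM, 3.72, SE 0.81, adjusted p = 0.11) had the smallest p in the lists of glial ion channels and of innate immune effectors and did not pass. srd-15, of the chemoreceptor families, was at 5.92 CPM against 0 counts in the non-AMsh group, at least 132-fold higher, and did not pass either (adjusted p = 0.171).

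**Figure D1:**
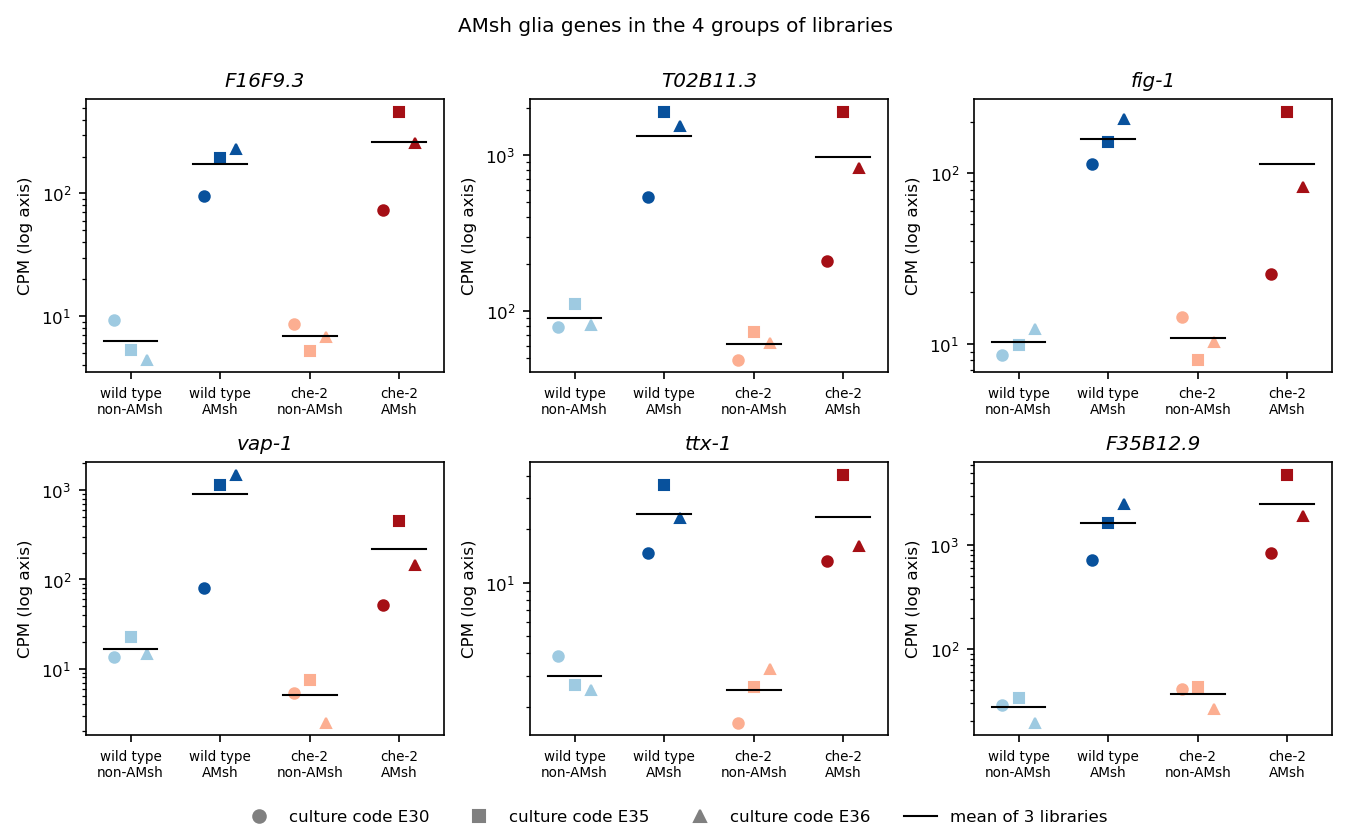
Level (CPM, log axis) of 6 AMsh-enriched genes in each of the 12 libraries by group, with symbols for the culture code and a line at the mean of 3 libraries. F16F9.3 averaged 173 CPM in wild type AMsh and 265 CPM in che-2 AMsh libraries, against 6.31 and 6.84 CPM in the non-AMsh libraries.

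The same comparison in che-2 shows which genes the sort enriched in the mutant. F35B12.9 was again among the highest (2519 ± 2053 against 36.9 ± 9.27 CPM, SD, n = 3, log2 fold change 6.09, SE 0.75, adjusted p = 0.00644), beside K02E11.7 (1309 ± 1131 against 21.9 ± 5.57 CPM, 5.90, SE 0.72, adjusted p = 0.00644). So was btb-18, a gene with a BTB domain (42.5 ± 28.2 against 0.566 ± 0.173 CPM, 6.22, SE 1.13, adjusted p = 0.0302). R08E5.4 was at 21.2 ± 17.1 against 0.323 ± 0.201 CPM (6.04, SE 1.199, adjusted p = 0.0481). C12D5.10 was at 7.59 ± 11.06 CPM against 1 count in the non-AMsh group (ratio interval 61.5 to 13635, adjusted p = 0.0438). F16F9.3 (265 ± 196 against 6.84 ± 1.70 CPM, 5.27, SE 0.69, adjusted p = 0.00644), T02B11.3 (3.98, SE 0.72, adjusted p = 0.0302), fig-1 (3.36, SE 0.65, adjusted p = 0.0432) and vap-1 (5.41, SE 1.07, adjusted p = 0.048) were higher. With the culture as a block, R08E5.4 (adjusted p = 0.0502, and 5.16e-07 to 1.00 over the alternatives run), fig-1 (0.268, and 1.95e-05 to 1.00) and vap-1 (0.076, and 2.87e-07 to 1.00) did not pass. ver-1 was at least 23.5-fold higher without passing (adjusted p = 1.00). Of the 22 AMsh markers, 6 were higher (7 higher and 1 lower adjusted over the list alone), among them ttx-1 (3.22, SE 0.56, adjusted p = 0.0228, and 0.0609 with the block) and far-8, which encodes a fatty acid and retinol binding protein (3.82, SE 0.73, adjusted p = 0.0418). Of the chemoreceptor families, 1 of 250 was higher (1 adjusted over the list alone), srr-1 (161 ± 165 against 8.38 ± 0.233 CPM, 4.27, SE 0.70, adjusted p = 0.0159, and 0.0551 with the block). Of the innate immune effectors, 1 of 112 was higher (2 adjusted over the list alone), the saposin-like gene spp-19 (4.67, SE 0.85, adjusted p = 0.0294, and 0.294 with the block). Of the glial ion channels and transporters, 0 of 41 passed (1 was higher adjusted over the list alone). kcc-3 had the smallest p there (154 ± 89.7 against 19.7 ± 8.71 CPM, 2.97, SE 0.62, adjusted p = 0.0652) and passed with the block (adjusted p = 0.0489).

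In che-2, 99 genes were higher and 0 lower in AMsh libraries by edgeR (497 at an unadjusted p under 0.05), none overlapping between groups, as for 8.08% of the tested genes (10% by chance). Of the 72 genes higher in wild type AMsh libraries, 71 were among the 99, where 0.427 were expected if the lists were independent. These fraction comparisons share no library, and log2 fold changes correlated across genes with r = 0.248 (genes are not independent replicates). With the replicate code as a block the count was 81 and with the culture as a block 82. DESeq2 called 183 genes, and the fit of these 6 libraries alone called 0 by edgeR. Leaving out single libraries gave 0 (without any of the che-2 non-AMsh libraries) to 127 genes (without che-2 AMsh E30), with 56 and 52 without che-2 AMsh E35 and E36.

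The central comparison, che-2 against wild type AMsh fractions, was led by genes that were high in every wild type library and near 0 in the mutant. The cuticle collagen gene col-50 (WBGene00000627, chromosome I, 3651230 to 3652599) was at 0.283 ± 0.411 CPM in che-2 and 1411 ± 1670 CPM in wild type (SD, n = 3, log2 fold change −12.25, SE 2.03, adjusted p = 0.0283). The saposin-like gene spp-18 (WBGene00005003, chromosome IV, 9593693 to 9594425) was at 0.190 ± 0.117 against 435 ± 235.04 CPM (−11.06, SE 1.35, adjusted p = 0.00959). asp-9, an aspartyl protease gene, was at 0.0602 ± 0.104 against 118 ± 106 CPM (−10.62, SE 1.43, adjusted p = 0.0129). In the other direction, spig-5 (WBGene00008797, chromosome V, 14308485 to 14308841) was at 232 ± 170 CPM in che-2 against 1.70 ± 0.433 CPM in wild type (7.09, SE 0.96, adjusted p = 0.0129). F57E7.4 (WBGene00077616, chromosome V, 16480336 to 16481019) was at 99.7 ± 64.8 against 4.36 ± 0.794 CPM (4.51, SE 0.74, adjusted p = 0.0279). The AMsh markers did not pass: the log2 fold change was 0.61 (SE 0.57, adjusted p = 0.705) for F16F9.3, −0.44 (SE 0.64, adjusted p = 0.829) for T02B11.3 and −0.49 (SE 0.59, adjusted p = 0.788) for fig-1. It was −2.06 (SE 0.92, adjusted p = 0.375) for vap-1 and −2.18 (SE 2.297, adjusted p = 0.75) for ver-1.

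Of the other genes that rose most, comp-1, named for its part in sperm competition, was at 9.75 ± 3.65 against 0.332 ± 0.256 CPM (4.85, SE 0.91, adjusted p = 0.0405). T22C1.8 (32.1 ± 12.2 against 2.04 ± 1.15 CPM, 3.97, SE 0.69, adjusted p = 0.0319) and Y54E2A.9 (26.7 ± 14.8 against 1.83 ± 0.738 CPM, 3.86, SE 0.66, adjusted p = 0.0312) rose too. B0511.11 (22.4 ± 4.56 against 1.74 ± 1.16 CPM, 3.68, SE 0.61, adjusted p = 0.0283) and WBGene00017211 (5.01 ± 2.44 against 0.238 ± 0.124 CPM, 4.36, SE 0.81, adjusted p = 0.0405) followed. K06H6.2, K06H6.1 and T05B4.9, all on chromosome V, had no count in wild type AMsh libraries and were at least 1525-fold, 480-fold and 269-fold higher in che-2. The reverse held for epic-3 (at least 987-fold lower), F47B8.14 (at least 916-fold), the secreted-protein gene scl-11 (at least 423-fold) and Y59A8B.19 (at least 383-fold), which had no count in che-2 AMsh libraries. ZK643.6 had 2 counts in che-2 against 99.8 ± 89.3 CPM in wild type (ratio interval 920 to 27446). col-185 (−12.11, SE 2.18, adjusted p = 0.0362), scl-13 (−11.28, SE 1.61, adjusted p = 0.0146) and col-35 (−11.18, SE 1.81, adjusted p = 0.0279) completed the 10 largest falls.

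**Figure D2:**
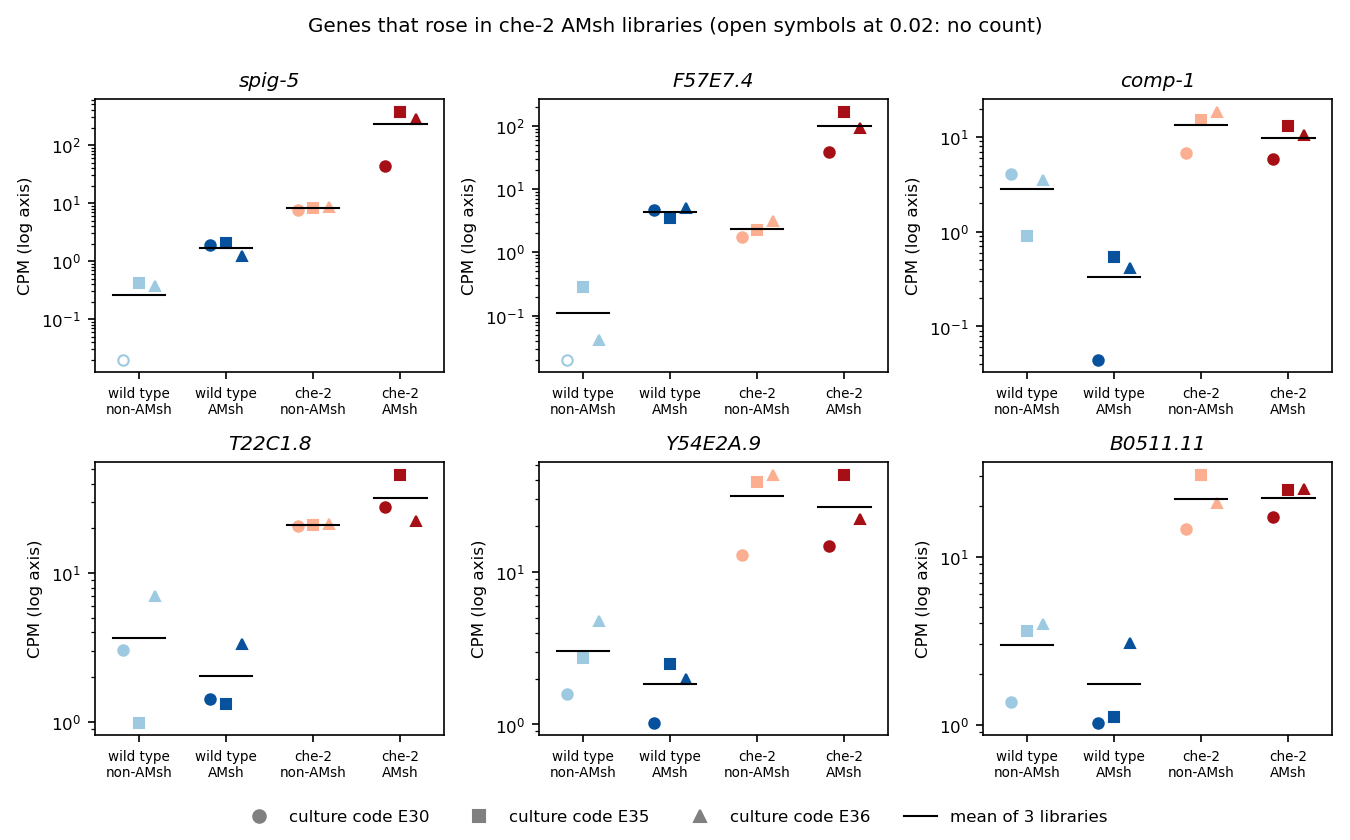
Level (CPM, log axis) in each library of 6 genes that rose in che-2 AMsh libraries, by group, with symbols for the culture code and a line at the mean of 3 libraries. spig-5 averaged 232 CPM in che-2 AMsh libraries against 1.70 CPM in wild type AMsh libraries.

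In total, 27 genes rose and 50 fell in che-2 AMsh libraries (2142 at an unadjusted p under 0.05), with a median log2 change of 0.12 over all tested genes. All 77 had no overlap between genotypes, as had 17% of the tested genes (10% by chance). DESeq2 called 883 genes, with more rises than falls (496 and 387), as did the fit without code E30 (183 and 74). The fit of these 6 libraries alone called 1 gene. Leaving out single libraries gave 0 (without che-2 AMsh E36) to 112 genes, with 14 without che-2 AMsh E35, 20 without wild type AMsh E35, 26 without wild type non-AMsh E35 or che-2 non-AMsh E36, 27 without che-2 AMsh E30 and 35 without wild type AMsh E30. Without the 2 libraries with the fewest detected genes, 26 genes were called, 21 of them among the 77.

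Among the fixed lists, the hypodermal and cuticle collagens held the most genes that fell: 13 of 169 measured members fell and 0 rose (30 fell and 1 rose adjusted over the list alone). They included col-108 (0.871 ± 0.477 against 113 ± 78.5 CPM, −7.0, SE 0.85, adjusted p = 0.00959) and col-158 (8.98 ± 3.42 against 2487 ± 2368 CPM, −8.11, SE 1.26, adjusted p = 0.0225). The list's mean was −0.98 and its median −0.03, which was above 0 with upper-quartile scaling, so the fall concerned part of the list (camera adjusted p = 9.95e-06, adjusted p = 0.588 with an estimated correlation). Of 107 genes of the apical extracellular matrix, 3 fell (11 adjusted over the list alone, median −0.73): grl-9 (−8.80, SE 1.49, adjusted p = 0.0283), grl-20 (1.67 ± 0.818 against 1039 ± 1188 CPM, −9.29, SE 1.66, adjusted p = 0.0355) and grl-24 (−8.85, SE 1.70, adjusted p = 0.0468), which encode ground-like domain proteins (list adjusted p = 2.53e-09, adjusted p = 0.588 with an estimated correlation). In the innate immune list spp-18 and the lectin gene clec-60 (−3.46, SE 0.64, adjusted p = 0.0405) fell, 2 of 112 (7 fell and 2 rose adjusted over the list alone, median −0.22, list adjusted p = 0.00855, adjusted p = 0.588 with an estimated correlation). The heat shock gene hsp-70 fell (59.7 ± 19.1 against 484 ± 246.2 CPM, −3.02, SE 0.57, adjusted p = 0.0432), 1 of 21 in its list (2 adjusted over the list alone, median −0.56, list adjusted p = 0.0011, adjusted p = 0.588 with an estimated correlation). asp-9 was the 1 of 58 lysosomal genes that fell (2 adjusted over the list alone, median −0.28, list adjusted p = 0.000122, adjusted p = 0.588 with an estimated correlation). With genes at or under 3 counts in a group set to their bound, the collagen and matrix medians were again −0.03 and −0.73, and the innate immune median was −0.20.

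Sperm genes were higher in che-2 as a list: 0 of 87 passed over all genes and 44 rose adjusted over the list alone (median 2.28, camera adjusted p = 2.14e-15, adjusted p = 0.588 with an estimated correlation). Their member with the smallest p, spe-6, was at 12.0 ± 2.76 against 2.49 ± 1.19 CPM (2.26, SE 0.56, adjusted p = 0.116). The median sperm gene stood at 2.65, 2.66 and 3.11 log2 CPM in wild type AMsh libraries E30, E35 and E36 and at 3.81, 5.50 and 4.72 in che-2, so a marker of gonad development differed between the genotypes together with the collagens. Of 4 measured vitellogenin genes, too few for a list test, 0 passed over all genes and 2 rose adjusted over the list alone (median 3.43), with vit-1 at 40.1 ± 43.5 against 1.07 ± 1.74 CPM (adjusted p = 0.161). Germ line genes (0 of 36 passed and 0 adjusted over the list alone, median 0.61) were also higher as a list (adjusted p = 0.0011, adjusted p = 0.647 with an estimated correlation). Ciliary and intraflagellar transport genes (0 of 60, 0 adjusted over the list alone, median 1.12) were higher as a list too (adjusted p = 0.000571, adjusted p = 0.588 with an estimated correlation). The ciliary gene dyf-3 was at 46.9 ± 25.2 against 11.9 ± 3.69 CPM (1.98, SE 0.50, adjusted p = 0.118). Lists that were lower with no passing member, also adjusted over the list alone, were the molting-cycle genes (33 genes, median −0.58, adjusted p = 0.000397), intestinal genes (22, −0.79, adjusted p = 0.00441) and neuropeptide genes (130, −0.10, adjusted p = 0.0264). With an estimated correlation, their adjusted p were 0.588, 0.588 and 0.768. Camera with an estimated correlation called 0 of the 31 lists in this comparison. The directional test of fry called 0 too, and its mixed test, which asks for changes in either direction, called 9: collagens, apical matrix, innate immune, heat shock, lysosomal, ciliary, oxidative stress, chemoreceptor and body wall muscle genes.

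The remaining 20 tested lists were not called by camera in the AMsh fraction, and none of their members passed over all genes. Adjusted over the list alone, 4 of 34 oxidative stress and detoxification genes fell (list adjusted p = 0.0531), 2 of 5 coelomocyte genes fell (0.138), and 1 of 47 histone genes rose (0.473, with a list median of 0.04, −0.06 with DESeq2 size factors, and a camera direction below the other genes). The list adjusted p was 0.154 for the AMsh markers (median −0.46), 0.141 for amphid channel genes (−0.57), 0.575 for glial ion channels, 0.502 for other glia, 0.187 for pan-neuronal genes, 0.223 for chemoreceptor families, 0.613 for body wall muscle, 0.502 for pharyngeal muscle and 0.913 for the excretory cell. It was 0.187 for basement membrane genes, 0.483 for the cytoskeleton, 0.0882 for endoplasmic reticulum chaperones, 0.213 for the secretory pathway, 0.357 for engulfment genes, 0.575 for mitochondrial stress genes, 0.114 for mitochondrially encoded genes and 0.227 for nuclear oxidative phosphorylation genes. The members closest to passing were srr-1 (161 ± 165 against 18.8 ± 4.42 CPM, 3.10, SE 0.66, adjusted p = 0.0732) and the glutathione S-transferase gene gst-10 (147 ± 27.2 against 540 ± 155 CPM, −1.87, SE 0.40, adjusted p = 0.0732). Next came a histone gene at the his-15 locus (WBGene00001885, 2.73 ± 2.01 CPM against 1 count, ratio interval 36.4 to 8147, adjusted p = 0.0834). Among glial genes, the channel gene delm-2 had no count in wild type AMsh libraries and was at least 45.5-fold higher in che-2 (2.08 ± 1.14 CPM, adjusted p = 0.171). The neurabin gene nab-1, of the dendrite anchoring list, had a log2 fold change of −1.24 (SE 0.48, adjusted p = 0.302).

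**Figure D3:**
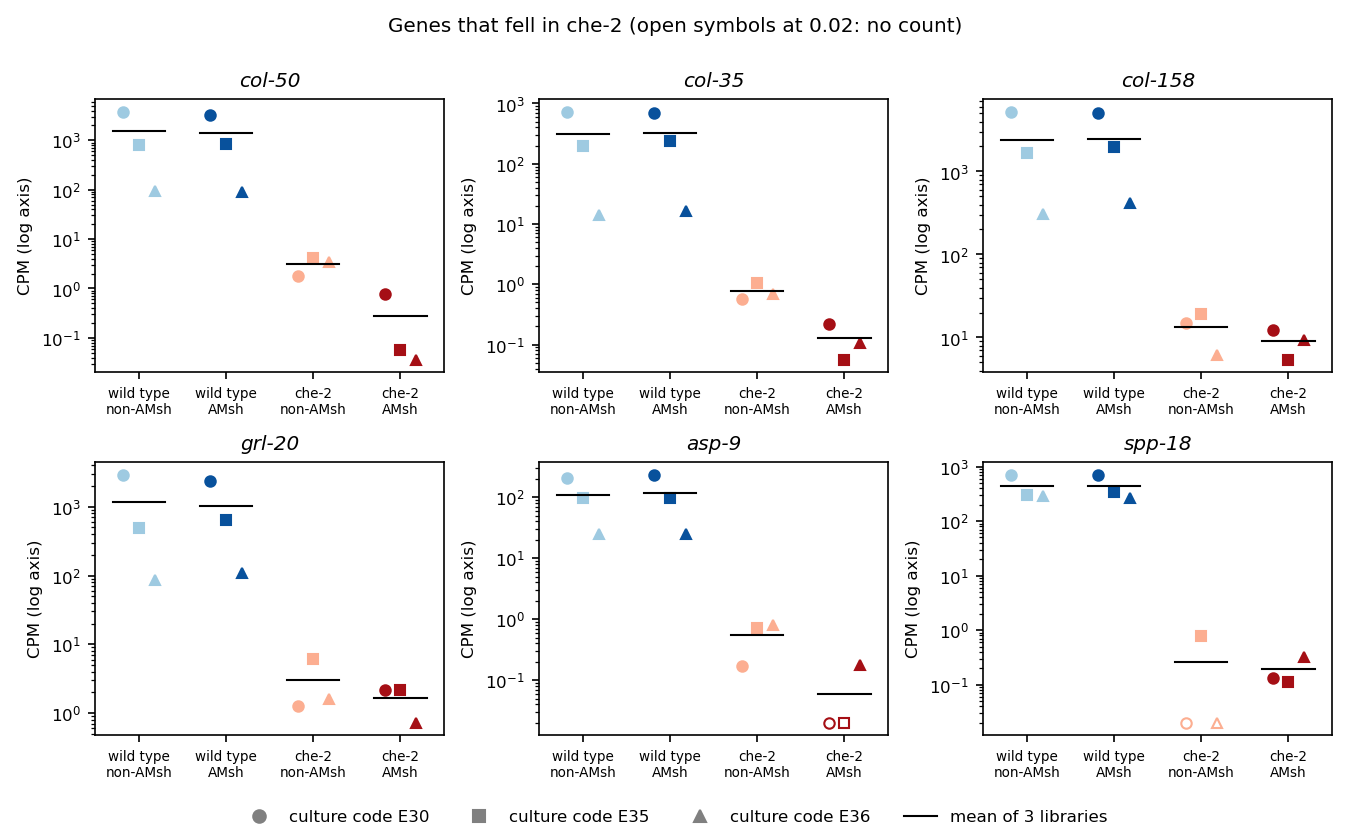
Level (CPM, log axis) in each library of 6 genes that fell in che-2 AMsh libraries, by group, with symbols for the culture code and a line at the mean of 3 libraries. col-50 averaged 1411 CPM in wild type AMsh and 0.283 CPM in che-2 AMsh libraries.

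The non-AMsh fractions show whether the change with che-2 also occurs in dsRed-negative cells. Over 7 tissue lists and 6 cultures, AMsh libraries held a median of 88.7% of the non-AMsh level. A change in the AMsh fraction therefore need not be one of the glia. Some of the same genes led, and no collagen gene was among the 10 largest falls that passed. The collagen gene col-183 fell further than some of those 10 (log2 fold change −9.42) without passing (adjusted p = 0.0691). col-50 and col-35 also stayed just above the threshold (adjusted p = 0.0633 and 0.0618). The gene spp-18 was at 0.255 ± 0.442 CPM in che-2 and 431 ± 237 CPM in wild type (SD, n = 3, log2 fold change −10.74, SE 1.33, adjusted p = 0.0175). ZK218.5 (WBGene00013939, chromosome V, 17101132 to 17101982) was at 0.208 ± 0.283 against 195 ± 67.97 CPM (−9.87, SE 1.23, adjusted p = 0.0175). Its neighbour ZK218.11 had no count in che-2 and 107 ± 90.7 CPM in wild type, at least 1904-fold lower (adjusted p = 0.0175). Among the genes that rose, Y69A2AR.19 was at 44.8 ± 17.2 against 3.46 ± 1.84 CPM (3.69, SE 0.48, adjusted p = 0.0175). Y113G7C.1 (2.23, SE 0.38, adjusted p = 0.0486) and Y43F8A.2 (2.15, SE 0.36, adjusted p = 0.0476) rose too. K06H6.1 had no count in wild type (at least 347-fold higher, adjusted p = 0.0476), and K06H6.2 was at 59.5 ± 34.3 CPM against 2 counts (ratio interval 570 to 17030, adjusted p = 0.0183). Further falls were those of Y59A8B.19 (at least 219-fold), ZK643.6 (2 counts, ratio interval 720 to 21489), F47B8.14 (1 count, 370 to 81497), the amino acid transporter gene aat-1 (2 counts, 89.3 to 2677), scl-13 (−9.09, SE 1.47), epic-3 (−8.90, SE 1.09) and asp-9 (−7.57, SE 1.22), with adjusted p from 0.0175 to 0.0476. The markers F16F9.3 (0.12, SE 0.58, adjusted p = 0.982), T02B11.3 (−0.55, SE 0.65, adjusted p = 0.865), fig-1 (0.10, SE 0.60, adjusted p = 0.985), vap-1 (−1.72, SE 0.92, adjusted p = 0.577) and ver-1 (no count in che-2 and 3 in wild type) did not pass.

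In total, 6 genes rose and 18 fell in che-2 non-AMsh libraries (1721 at an unadjusted p under 0.05). All 24 had no overlap between genotypes, as had 22.2% of the tested genes (10% by chance). Of the 6 that rose, 5 were among the 27 that rose in AMsh libraries (0.00971 expected if independent), and all 18 that fell were among the 50 that fell there (0.0539 expected). All 50 had an unadjusted p under 0.05 with the same sign in the non-AMsh fraction, and 25 of the 27. The fractions use different libraries from the same cultures, so these overlaps are not independent repeats, and r across genes between the changes was 0.664. DESeq2 called 778 genes and limma-voom 974, both with more rises than falls (453 and 325, 610 and 364), as had the fit without code E30 (23 and 16). DESeq2 size factors in edgeR gave 14 genes and the fit of these 6 libraries alone 11. Leaving out single libraries gave 0 (without che-2 non-AMsh E30 or E36, or wild type non-AMsh E35) to 102 genes (without wild type AMsh E30). It gave 2 without che-2 non-AMsh E35, 5 without wild type non-AMsh E30, 10 without che-2 AMsh E36, 12 without wild type AMsh E35, 38 without wild type AMsh E36 and 46 without wild type non-AMsh E36. Without the 2 libraries with the fewest detected genes, 290 genes were called, including all 24.

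**Figure D4:**
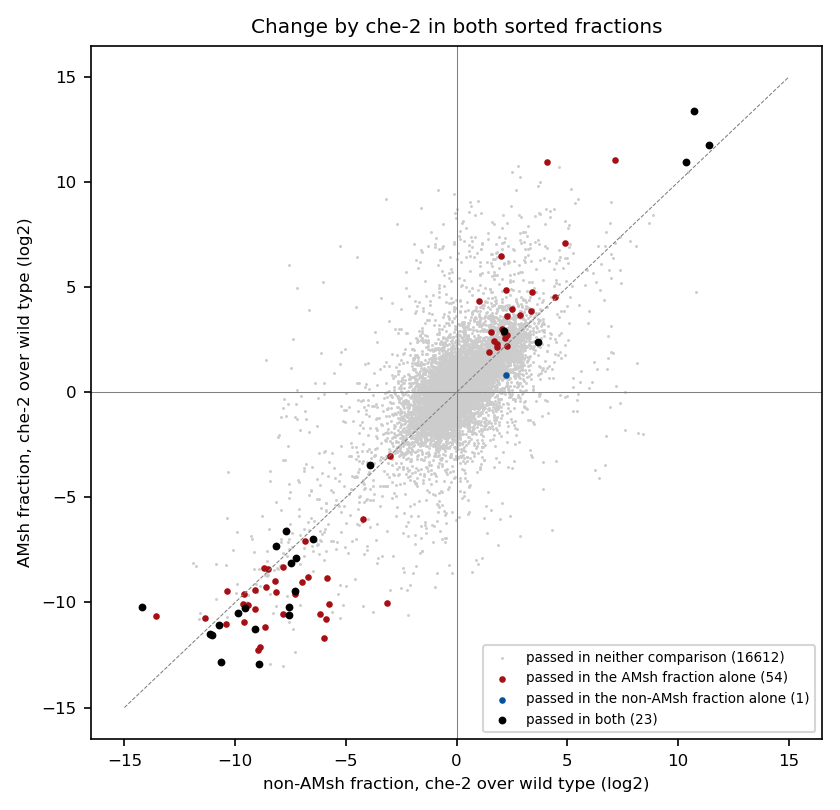
Log2 fold change of che-2 against wild type in non-AMsh (x) and AMsh (y) fractions, 1 point per tested gene, coloured by where the gene passed. In the AMsh fraction alone 54 genes passed, in both fractions 23, and in the non-AMsh fraction alone 1.

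By list, 49 of 87 sperm genes rose adjusted over the list alone in the non-AMsh fraction and 0 over all genes (median 2.60, adjusted p = 2.38e-28, adjusted p = 0.427 with an estimated correlation). The sperm gene spe-11 was at 47.3 ± 22 against 6.34 ± 3.47 CPM (2.90, SE 0.62, adjusted p = 0.0838). The median sperm gene stood at 1.82, 2.87 and 3.92 log2 CPM in wild type libraries E30, E35 and E36 and at 3.95, 5.70 and 5.73 in che-2. The 4 vitellogenins had a median of 3.86, with 2 risers adjusted over the list alone. Of 169 collagens, 2 fell (28 adjusted over the list alone, mean −1.03, median −0.01): col-108 (1.06 ± 0.773 against 96.1 ± 9.49 CPM, −6.49, SE 0.83, adjusted p = 0.0175) and col-158 (−7.48, SE 1.23, adjusted p = 0.0476). The list adjusted p was 0.00152, and 0.54 with an estimated correlation. In the apical matrix list 0 of 107 passed (14 fell adjusted over the list alone, median −0.76, adjusted p = 8.34e-08, adjusted p = 0.427 with an estimated correlation). spp-18 and clec-60 (−3.89, SE 0.66, adjusted p = 0.0476) were the 2 of 112 innate immune genes that fell (8 adjusted over the list alone, median −0.42, list adjusted p = 0.000113, adjusted p = 0.427 with an estimated correlation). asp-9 was 1 of 58 lysosomal genes that fell (1 adjusted over the list alone, median −0.47, list adjusted p = 3.05e-05, adjusted p = 0.54 with an estimated correlation). hsp-70 did not pass (53.2 ± 30.01 against 422 ± 187 CPM, −2.99, SE 0.57, adjusted p = 0.0624; 1 of 21 heat shock genes fell adjusted over the list alone, median −0.48, list adjusted p = 0.00123, adjusted p = 0.54 with an estimated correlation).

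The other lists called in the non-AMsh fraction had 0 passing members over all genes, and 0 of them were called with an estimated correlation, whose adjusted p is the second given. Neuropeptide genes were lower (130 genes, median −0.67, adjusted p = 4.02e-08 and 0.54). Also lower were the molting-cycle (33, −0.51, adjusted p = 0.00152 and 0.564), intestinal (22, −0.90, adjusted p = 0.00405 and 0.54), mitochondrially encoded (12, −0.42, adjusted p = 0.0172 and 0.611) and chemoreceptor genes (250, −0.53, adjusted p = 0.0222 and 0.54), with 0 members adjusted over the list alone in each. Oxidative stress genes (34, −0.43, adjusted p = 0.00834 and 0.399, 1 fell adjusted over the list alone) and coelomocyte genes (5, −1.47, adjusted p = 0.0227 and 0.54, 2 fell adjusted over the list alone) were lower too. Germ line genes (36, 0.73, adjusted p = 4.68e-05 and 0.564, 0 adjusted over the list alone) and ciliary genes (60, 0.66, adjusted p = 0.0395 and 0.611, 1 rose adjusted over the list alone) were higher. The ciliary gene dyf-3 was at 37.4 ± 9.94 against 7.18 ± 3.10 CPM (2.38, SE 0.51, adjusted p = 0.0815). The directional test of fry called 0 lists and its mixed test 5 (collagens, innate immune, heat shock, lysosomal and oxidative stress genes). The other 16 tested lists were not called by camera. The members of smallest p of the neuropeptide and oxidative stress lists, flp-27 (−1.42, SE 0.32, adjusted p = 0.106) and the metallothionein gene mtl-1 (−5.69, SE 1.36, adjusted p = 0.118), did not pass.

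**Figure D5:**
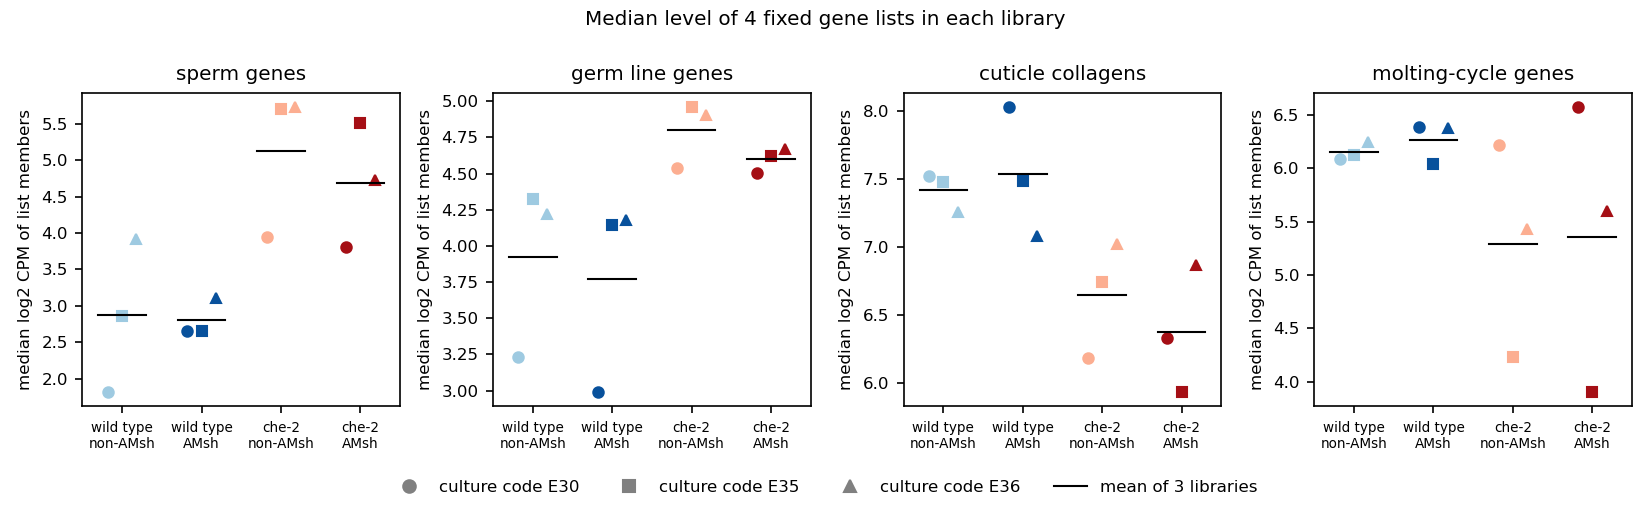
Median level (log2 CPM) of the members of 4 gene lists in each library, by group, with symbols for the culture code and a line at the mean of 3 libraries. Sperm genes stood between 1.82 and 3.92 in wild type and between 3.81 and 5.73 in che-2 libraries.

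The test of whether the che-2 change differs between the AMsh and non-AMsh fractions asks for a response particular to the AMsh fraction. AMsh libraries held a median of 88.7% of the non-AMsh level of the tissue lists. A glial change in a gene also expressed in other cells could thus be hidden. A lack of passing genes therefore does not show that the glia did not respond. The genes with the smallest p, none of which passed, had low levels: K10C2.2 (2.48 ± 1.35 in che-2 and 0.0996 ± 0.0505 CPM in wild type AMsh libraries, against 0.717 ± 0.577 and 3.20 ± 3.05 CPM in non-AMsh libraries, SD, n = 3), W03G9.9, Y38E10A.14, WBGene00010095 and pax-3. Their fitted log2 differences were 6.71 (SE 1.53), 10.40 (SE 2.24), 8.21 (SE 1.95), −8.31 (SE 1.98) and 10.70 (SE 2.66), of which the last 4 rest on a group with no count and are no bounds. The markers differed by 0.50 (SE 0.82, F16F9.3), 0.11 (SE 0.91, T02B11.3), −0.59 (SE 0.84, fig-1), −0.34 (SE 1.26, vap-1) and 0.94 (SE 1.95, ver-1). By edgeR 0 genes passed (281 at an unadjusted p under 0.05, smallest adjusted p = 1.00), limma-voom called 0 and DESeq2 called 4, npr-11, srbc-51, W03G9.9 and K10C2.2, each with at most 3.27 CPM in any group. spig-5 and F57E7.4, which rose in AMsh libraries, had non-AMsh changes of 4.91 (SE 0.92, adjusted p = 0.0618) and 4.43 (SE 0.84, adjusted p = 0.0624), and the differences of 2.18 and 0.09 did not pass (edgeR adjusted p = 1.00 each). Neuropeptide genes changed less downward in AMsh than in non-AMsh libraries as a list (median difference 0.45, camera adjusted p = 0.00825, adjusted p = 0.995 with an estimated correlation). The change of sperm genes was smaller (median difference −0.17, adjusted p = 0.0335, adjusted p = 0.995 with an estimated correlation). Both tests of fry called 0 lists, and 1 list was called by camera with DESeq2 size factors or without code E30 or E35. The other 29 tested lists were not called.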

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

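The tests of the culture order, of a single culture, of older animals, of other tissues, of the gate and of the number of neighbouring genes were chosen after the results they bear on were seen; the tests of the dauer commitment reporters, of the culture order of the neighbouring genes and of other splits of the libraries were set before, and how the tests of the culture orders, of a single culture, of older animals, of the gate and of the number of neighbouring genes are made or read was changed after values were seen.

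Neuropeptide genes stood out because their che-2 change differed between the fractions (adjusted p = 0.00825, median difference 0.45, adjusted p = 0.995 with an estimated correlation). Sperm genes stood out for the same reason, in the opposite direction (adjusted p = 0.0335, median difference −0.17, adjusted p = 0.995 with an estimated correlation).

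Among the genes that fell, cuticle collagen genes were far lower in che-2 than in wild type; 33 of the 50 fallen genes (66%) had wild type non-AMsh levels in the order E30 over E35 over E36, against 15.8% of tested genes, but this order was taken from the fallen genes, which may change together, so it leaves open larvae on the dauer route in the wild type cultures, a route that mutants without normal cilia enter poorly. Of 4 reporters of dauer commitment, 2 had every wild type library above every che-2 library (col-183, mean 5372 against 7.28 CPM, and nhr-246, 10.3 against 0.217 CPM) and ets-10 and F53F1.4 did not, so the reporters left that route open too. In 48 of the 50 (96%), the lowest wild type non-AMsh library was over 4-fold above the highest che-2 one. The median gap was 21.6-fold, with 3 counts as the floor per library. These 48 genes were thus above che-2 in every wild type culture. All 50 were chosen by a fall without overlap in AMsh libraries of the same cultures, which favours such a gap. The gap therefore cannot decide whether a single wild type culture was the source of differences beyond these genes. The calls depended on single codes. Of the 77 genes, 58 (75.3%) were still called without code E30, 1 without E35 and 0 without E36. Without wild type AMsh E30, E35 and E36, 32, 16 and 60 were still called. Older animals in the che-2 cultures stay open: sperm genes were higher by a median log2 change of 2.60 in the non-AMsh fraction, but the lowest che-2 library lay above the highest wild type one by 0.0282, less than the wild type SD of 1.05, and at that like sperm level col-2 was at 3.25 CPM in che-2 E30 and 560 CPM in wild type E36, and the adult collagen gene col-19 at 23.4 and 288 CPM. Whether loss of cilia acts on these genes in any other way was not tested, because each genotype was grown in its own cultures.

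Transcripts of other cell types were abundant in the dsRed-positive fraction: over 7 tissue lists and 6 cultures, the AMsh libraries held a median of 88.7% of the non-AMsh level, with list medians from 80.5% for germ line genes to 105% for pan-neuronal genes and single values from 44.5 to 140% (coelomocyte genes in wild type E30 and E35), and the muscle myosin gene unc-54 was at 1894 ± 324 CPM in wild type AMsh against 1584 ± 71.0 CPM in non-AMsh libraries. This is consistent with cells or RNA of other tissues in the sorted fraction, which the dsRed gate was meant to remove, although AMsh glia may express some of these genes themselves. A gate that did not separate dsRed-positive cells at all was argued against: the median ratio of the 5 fixed markers between the fractions was at least 6.82 in each of the 6 cultures (3 counts as the floor per library), with F16F9.3, T02B11.3 and vap-1 over 4-fold higher in all 6, fig-1 in 5 (1.78-fold to 28.3-fold) and ver-1 not detected in every culture. The genes enriched in wild type AMsh libraries, chosen for that difference in part of these libraries, took 0.872 to 5.01% of the counts in AMsh libraries and 0.0937 to 0.122% in non-AMsh libraries.

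Among genes that differed at least 100-fold without overlap, 86 were lower in che-2 (means there up to 11.7 CPM, 46 of them passing in AMsh libraries and 17 in non-AMsh) and 9 lower in wild type (up to 0.981 CPM), and 3 neighbours on chromosome V (ZK218.5, ZK218.7 and ZK218.11, 17101132 to 17108418) fell together. The left neighbour ZK218.4 was detected in both strains (mean 3.57 CPM in wild type and 2.81 CPM in che-2) but had no count in che-2 non-AMsh libraries, and the right neighbour WBGene00045492 (0.619 CPM in wild type) had no count in che-2. Random placements seldom gave such a run: 4 of 1000 gave 3 genes in runs and none gave more, with a mean of 0.012 genes. The bar for excluding changes of single genes at independent places was a number above every placement, set after values were seen. It was not reached, so such changes were not excluded. The dauer route stays open for this run: 0% of its 3 genes had the culture order E30 over E35 over E36, against 83.1% of the 83 other genes at least 100-fold lower in che-2, but the bound set beforehand, any lower share, was too weak, since neighbours can change as 1 event and 14 of the 83 lacked the order too (share 0.179 with the run counted once). A difference between the strains at this place could remain and was not tested, as reads were not used here.

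The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and the real split was the 1 with as many genes in each case. The real values were 77, 24, 73 and 99 genes for che-2 in AMsh, che-2 in non-AMsh, the fractions in wild type and the fractions in che-2, and the highest of the other splits was 0 in each. Those other splits put libraries of both real groups on each side. Large differences between the real groups then widen the spread within each side, which favours 0 calls. The contrast with 0 is therefore no support for the calls. For the difference between changes, the 20 assignments of the AMsh genotype labels are too few as well: the real value was 0, so all 20 gave as many, and the highest other was 852, from the mirrored labels, which add the changes of both fractions instead of subtracting them and so count the change they share.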

How the results depend on the processing

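The fit without the 2 libraries with the fewest detected genes was chosen after the data were seen; the other alternatives were planned. Why a count moved was not tested. No gene named by the size of change or as an AMsh marker that passed under either setting changed direction, and the che-2 transcript level moved by less than its SD in each group with unscaled totals. The balance of rises and falls did turn. In AMsh libraries 27 rose and 50 fell, against 496 and 387 with DESeq2, 183 and 74 without code E30, and 1 and 0 without code E35. The replicate code as a block gave 112 and 106 there. In non-AMsh libraries 6 rose and 18 fell, against 453 and 325 with DESeq2, 610 and 364 with limma-voom and 154 and 136 without the 2 libraries with the fewest detected genes. Without code E30 the counts were 23 and 16, without code E35 1 and 0, and with the replicate code as a block 84 and 83. Medians of lists near 0 also changed sign with scaling, among them the collagens (−0.03, and 0.00 with upper-quartile scaling) and histones (0.04, and −0.06 with DESeq2 size factors) in AMsh libraries. For che-2 against wild type in AMsh libraries (77 genes), scaling, the stricter filter, robust dispersion, a 2-fold minimum and limma-voom gave 72 to 80 (limma-voom shared 46 of the 77). The count was 198 with no filter, 883 with DESeq2, 190 at a false discovery rate of 0.1, 1 with only the 6 libraries compared and 26 without the 2 libraries with the fewest detected genes. Leaving out libraries or codes gave 0 to 257: 0 without che-2 AMsh E36 or code E36, 1 without code E35, 14 without che-2 AMsh E35, 20 without wild type AMsh E35, 26 without wild type non-AMsh E35 or che-2 non-AMsh E36, 27 without che-2 AMsh E30, 35 without wild type AMsh E30 and 257 without code E30. Where 1 or 2 libraries are left in a group, they are assumed to vary like the other groups.

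In non-AMsh libraries (24 genes) upper-quartile scaling, the stricter filter, robust dispersion and a 2-fold minimum gave 17 to 28. The count was 14 with DESeq2 size factors, 209 with no filter, 778 with DESeq2, 974 with limma-voom, 11 with only the 6 libraries compared, 133 at a false discovery rate of 0.1 and 290 without the 2 libraries with the fewest detected genes. Leaving out libraries or codes gave 0 to 102: 0 without che-2 non-AMsh E30, che-2 non-AMsh E36, wild type non-AMsh E35 or code E36, 1 without code E35, 2 without che-2 non-AMsh E35, 5 without wild type non-AMsh E30, 10 without che-2 AMsh E36, 12 without wild type AMsh E35, 38 without wild type AMsh E36, 39 without code E30, 46 without wild type non-AMsh E36 and 102 without wild type AMsh E30. For the difference between changes, DESeq2 called 4 genes and every other alternative run 0.

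With the replicate code as a block, 218 genes passed in AMsh libraries (112 rose and 106 fell) and 167 in non-AMsh libraries (84 rose and 83 fell). Wild type and che-2 libraries of the same code are different animals and share a code whose meaning the labels do not give: their correlation across genes was −0.00 to 0.0395 in AMsh libraries, where 2 of 3 correlated best with their own code, and 0.0769 to 0.201 in non-AMsh libraries, where 3 of 3 did.

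For the fractions in wild type (73 genes), DESeq2 gave 176 and the fit without the 2 libraries with the fewest detected genes 111, and the other settings with all replicates 65 to 99. Leaving out libraries or codes gave 0 to 97: 0 without wild type non-AMsh E35, wild type non-AMsh E36, code E35 or code E36, 19 without wild type non-AMsh E30, 42 without wild type AMsh E35 and 97 without code E30. With the culture as a block, fig-1, vap-1, ttx-1, C18D1.2, F59D12.3 and WBGene00017211 lost their call in wild type. In che-2, fig-1, vap-1, ttx-1, srr-1, spp-19 and R08E5.4 lost theirs and kcc-3 passed, and the block changed no other call of a named gene. For the fractions in che-2 (99 genes), DESeq2 gave 183, only the 6 libraries compared 0, and the other settings with all replicates 81 to 128. Leaving out libraries or codes gave 0 to 137: 0 without any single che-2 non-AMsh library, code E35 or code E36, 52 and 56 without che-2 AMsh E36 and E35, and 137 without code E30.

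Of the lists, 11 were called in AMsh and 15 in non-AMsh libraries (10 to 13 and 12 to 18 with a code left out), and 0 with an estimated correlation or with the directional test of fry, whose mixed test called 9 and 5. For the difference between changes, 2 were called, 0 with an estimated correlation or with either test of fry, 1 with DESeq2 size factors, and 1 to 2 with a code left out (1 without E30 or E35). For the fractions in wild type, the AMsh markers were called with the preset correlation in each setting run, as the 1 list except without code E30 (5), so the range with a code left out was 1 to 5. With an estimated correlation, their adjusted p of 0.0418 became 0.0526 with DESeq2 size factors and 0.097 with the replicate code as a block. It became 0.195, 0.534 and 0.981 without codes E30, E35 and E36. For genes named by the size of change or as AMsh markers (members named from lists alone were left out here), over all comparisons and settings, 1329 results stayed on their side of the threshold, 562 lost their call and 1 newly passed. With totals of 15420762 to 26019499 counts, a gene with no count in a library had at most 0.115 to 0.195 CPM there. On simulated counts, edgeR recovered 10% of genes with a mean of at least 5 CPM that were changed 4-fold in AMsh libraries.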

Other observations

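The genes and values below were chosen after they were seen, and no test beyond the comparisons above was run on them.

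Stage-related genes differed between cultures of the same genotype. In non-AMsh libraries E30, E35 and E36, the adult collagen gene col-19 was at 23.4, 2604 and 697 CPM in che-2 and at 22.4, 92.3 and 288 CPM in wild type. The yolk gene vit-2 was at 5.86, 444 and 105 CPM in che-2 and the sperm gene msp-19 at 49.7, 508 and 525 CPM. In che-2 AMsh libraries, col-19 was at 19.4, 3417 and 370 CPM, vit-2 at 0.981, 344 and 46.6 CPM and msp-19 at 53.9, 389 and 138.5 CPM. The dauer collagen gene col-2 was at 16645, 3464 and 560 CPM in the wild type non-AMsh libraries E30, E35 and E36, and at 3.25, 20.3 and 2.297 CPM in che-2. Of genes read beside it, col-40, cut-1, mtl-1, sod-3, hsp-12.6 and tts-1 had every wild type library above every che-2 library. For cut-1 the lowest wild type level was 20.4 CPM and the highest che-2 level 1.91 CPM, and for mtl-1 19.3 and 12.0 CPM. The genotypes overlapped for icl-1, lea-1 and daf-28.

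Groups of neighbouring genes at separate places on chromosome V were detected in che-2 and nearly undetected in wild type. They lay near K06H6.2 (585778 to 587250) and near T05B4.10 (4119890 to 4120729). Of the genes at least 100-fold lower in wild type without overlap, 0 stood in runs of 3 or more neighbours. K06H6.4 was at 1.49 ± 2.19 CPM in che-2 AMsh libraries (SD, n = 3), nstp-7 at 1.96 ± 2.99 CPM and ZK488.6 at 2.01 ± 2.304 CPM, beside K06H6.2 (60.05 ± 49.1 CPM) and K06H6.1 (19.6 ± 14.9 CPM), and none had a count in wild type AMsh libraries. T05B4.8 (5.83 ± 0.554 CPM), T05B4.9 (11.29 ± 3.09 CPM) and T05B4.10 (11.4 ± 2.89 CPM) also lacked any count in wild type AMsh libraries. In wild type non-AMsh libraries, T05B4.9 was at 0.927 ± 1.21 CPM and T05B4.8 at 0.482 ± 0.766 CPM.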
